A study of Bacillus subtilis subsp. subtilis NCIB 3610 = ATCC 6051 = DSM 10 with 42 samples.

How the data were processed

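The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Bacillus subtilis with antibodies against DegU or SwrA, together with the control DNA of the same strains. There were 42 libraries. The DegU antibody was used in 20 of them and the SwrA antibody in 8, and 14 were controls, either crosslinked DNA taken without antibody (called input) or whole-genome sequencing (WGS). Per the labels' protocols, cells were grown in rich broth (LB), crosslinked with formaldehyde, lysed, and sheared to fragments of about 200 bp. Replicates within a group are separate biological samples, per the series design.

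The deposited files give sequencing coverage per base, as the authors made it with CLC Genomics Workbench on the chromosome of the strain studied, per the labels' protocols. The version and settings of that program are not given in the sources used here. Ribosomal RNA loci had been removed by the authors, per the labels' protocols, and 0.766% of the 4215607 positions were at 0 in every library. No pair of libraries had identical files (0 pairs). Mean coverage per base ran from 16.9 to 89.1 in the 28 ChIP libraries and from 21.1 to 82.1 in the 14 controls.

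From these values, the coverage of each library was divided by its own mean per base, which gives relative coverage, and averaged in 200 bp bins. Each ChIP value was then the log2 ratio of relative coverage to that of the control DNA of the same strain, after adding 0.1 to both, and is called enrichment. Where several inputs were titled for the same strain and antibody, their mean was used, and wild-type inputs served both antibodies. The DegU ChIP of ΔdegU and the SwrA ChIP of ΔswrA each had 1 such input. Any error in it is common to both replicates. The 4 strains with a Physpank construct had 1 WGS library each as their control, in place of an input. The labels give the same fixation for WGS as for input, so whether the WGS DNA was crosslinked is not settled. Bins with relative control coverage under 0.25 were left out, which kept 20278 of 21078 bins.

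Sites were called with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, over all 20 DegU or all 8 SwrA ChIP libraries, so that every group shared an estimate of the spread. A bin was called when its log2 fold over the deletion control was at least 1 and its Benjamini-Hochberg adjusted p over all bins was under 0.05. The deletion control was the ΔdegU strain for the DegU antibody and the ΔswrA strain for the SwrA antibody, with 2 libraries each. Called bins closer than 400 bp were merged. The DegU sites of the 6 strains that have DegU gave a union of 476 sites. The value of a site was its enrichment in the 200 bp centred on the summit of the mean of the 6 strains. Strain contrasts and their interactions were tested by limma on these values, with adjustment over the 476 sites and no fold limit. A fitted adjusted p rests on limma throughout. Where a left-out library leaves a control with 1 library, limma assumes that it varies like the other groups.

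The fla/che promoter was tested by an exact permutation test, two-sided, that rearranged the libraries with and without swrA within each of 3 backgrounds (8000 arrangements, smallest possible p 0.00025). Within a background, 3 libraries against 3 allow no p below 0.1. Peak width at this promoter was taken in 10 bp bins over 4000 bp, at 0.5 of the summit height above the median of the outer 500 bp on each side. Shared DegU and SwrA sites were those that overlapped by at least 1 bp, set against 1000 random placements of the SwrA sites.

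No genome sequence was used, and gene names came from a table of another assembly of the same strain that gives no strand. Of its 4535 genes, 4435 lie on the chromosome. Names were placed by aligning the table's pattern of genes and gaps with the faint coverage pattern of the 4 ChIP libraries whose antigen is deleted. The offset between the frames was 442 bp before and 4783 bp after a stretch from 1941 to 2015 kb in which no name could be placed. Positions are those of the authors' chromosome build. Without strand, a site could not be named for the nearest start codon as planned. It is named for the gene it lies in or for both neighbours, and locus tags stand for genes without a symbol.

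The 6 gene lists were flagellar and chemotaxis promoters, secreted degradative enzymes, biofilm and capsule, competence, Deg regulators, and housekeeping as a comparison list. A gene window ran from 400 bp outside to 100 bp inside each of its 2 ends, and the called end, or else the end of larger fold, was taken, because the start could not be told from the end. A gene passed at a log2 fold of at least 0.5 over the deletion control and an adjusted p under 0.05 over 4300 genes. Each list was set against all other genes by a one-sided Fisher's exact test, adjusted over the lists. The test takes genes as independent, but a single bound stretch can pass the genes on both sides of it. Its p values may therefore be too small.

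The groups, comparisons, gene lists, site rule and the following naming rule were fixed before the data were examined. Named are the fla/che promoter, the 20 sites of largest fold per wild-type list (10 for other strains), up to 10 sites of largest rise and fall per strain contrast, and up to 4 members per gene list, from which the text takes a part. Sites and genes named outside that rule are said to be so. The alternatives were scaling by the median bin, a pseudocount of 0.5, no filter on the control, 1000 bp bins, no division by the control, a number-matched control, a log2 fold of at least 2, only the compared groups in the fit, a replicate block, gene windows from 200 bp outside to the gene end, and leaving out each library in turn. With the number-matched control, each ChIP library was divided by the control library of its own replicate number, or by the mean where there was none. Those added after the data were seen were sites also above their own control, and the mean of the 3 other WGS libraries as the control of the strain labelled ΔdegU Physpank-degU32.

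The calls were tested on values drawn from a normal distribution with the spread of each bin or site in these libraries, with known changes added. Such values hold no error of a shared control and no shift by scaling, so recovery in the real data may differ. Of 200 bins raised by a log2 of 1, 51% were called for DegU and 30.5% for SwrA, and of those raised by 2, 98% and 88.5%. At the level of sites, changes of 1 between ΔswrA and wild type were found in 82% of 50 changed sites, and interactions of 1 and 2 in 42% and 92%. Files were read with Python 3.11.15 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.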

Results

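DNA bound by DegU and by SwrA was measured in an undomesticated strain of Bacillus subtilis that swarms. DegU is a response regulator that the kinase DegS phosphorylates, and SwrA is a protein needed for swarming that acts with DegU on flagellar genes. The DegU antibody was used on 3 libraries each of wild type, Physpank-degQ, the strain labelled ΔdegU Physpank-degU32, ΔswrA, ΔswrA Physpank-degQ and the strain labelled ΔdegU ΔswrA Physpank-degU32, and on 2 of ΔdegU. Physpank is an inducible promoter, degQ encodes a small protein that raises the phosphorylation of DegU, and degU32 encodes a hyperactive DegU. The SwrA antibody was used on 3 libraries of wild type, 2 of ΔswrA and 3 of ΔdegU. Mean coverage per base was 16.9 to 89.1 in the 28 ChIP libraries, with a median of 54.3, and 21.1 to 82.1 in the 14 controls, with a median of 45.8.

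The deleted and added genes were looked at in every library before any comparison. Relative coverage of degU over its flanks was 0.03 to 0.08 in the libraries labelled ΔdegU without a construct. For swrA the ratio was 0.05 to 0.08 in the ΔswrA inputs and at most 0.38 in every other library labelled ΔswrA. Replicate 1 of the SwrA ChIP libraries labelled ΔdegU, which should carry swrA, stood at 0.14, against 0.71 and 0.89 in replicates 2 and 3. Only 11 of 3616 genes in that library were as low relative to their flanks. The value goes against the label, but that library was shallow (mean coverage 23.3) and uneven, with 275 genes under 0.5 of their flanks, against 10 to 12 in the SwrA libraries of wild type. Both inputs of that strain carried swrA, at 0.92 and 0.97 of its flanks. Whether the library lacks swrA or is unevenly covered was thus not settled, and it is called the library labelled ΔdegU replicate 1. In WGS, degQ stood at 2.49 and 2.42 times its flanks in the 2 Physpank-degQ strains. In WGS of the 2 strains labelled ΔdegU with Physpank-degU32, degU stood at 2.17 and 2.03 times its flanks, against 1.03 and 1.01 in the Physpank-degQ strains. Coverage thus stood near 2 copies where the labels give 1, and both strains are called labelled throughout. The capsule synthesis gene pgsB had next to no coverage in WGS of any of the 4 Physpank strains, from 3699091 to 3700600.

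In wild type, the DegU sites of largest fold lay at genes of several functions, chemotaxis among them. The largest folds over ΔdegU were in tlpA, a chemotaxis receptor gene (log2 fold 7.41, SE 0.63, adjusted p = 5.1e-07, 3208001 to 3208600), in yneI, beside the cytochrome biogenesis gene ccdA (6.95, SE 0.53, adjusted p = 3.29e-07, 1923801 to 1924400), and between the extracellular protease gene epr and sacX (6.58, SE 0.54, adjusted p = 3.29e-07, 3941601 to 3942200). Next came 6.38 between EJJ34_RS23105 and EJJ34_RS21175 and 5.69 in yrvJ. Between codY and flgB, the start of the fla/che operon of flagellar and chemotaxis genes, the fold was 5.54 (SE 0.58, adjusted p = 1.29e-05). Other folds among the 20 largest were 5.66 in yvyF, which lies before the anti-sigma factor gene flgM, 5.50 between the division gene ftsZ and the protease gene bpr, 4.76 between hxlR and the surfactin synthetase gene srfAA, 3.98 between swrA and ctpB, and 3.85 between slrC and the biofilm regulator gene slrA. limma called 47 sites, of which 27 had their summit between genes and 19 within a gene, with a median log2 fold of 3.17 and a median width of 400 bp. Bins at least 2-fold below ΔdegU, the same call in the other direction, numbered 32 against 82 above it. Of the 47 sites 3, in EJJ34_RS04115, gabT and cydD, lay below their own input. The count rested on the control, at 22 sites without ΔdegU replicate 2 and 25 without replicate 1, and was 26 with 1000 bp bins and 78 with only both groups in the fit.

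**Figure D1:**
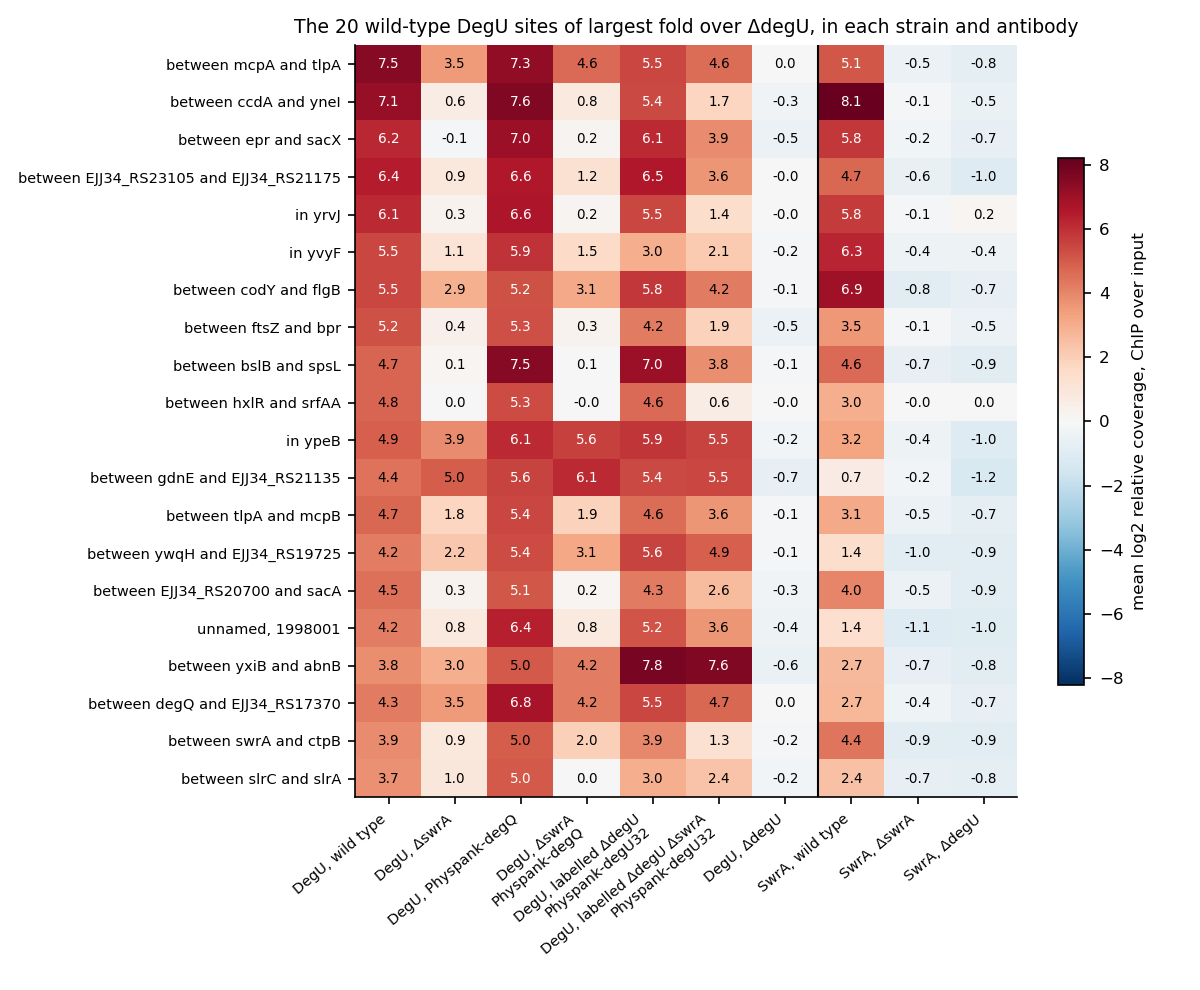
Mean enrichment (log2 relative coverage of ChIP over control DNA, colour and printed value, 3 libraries per column or 2 for ΔdegU with DegU and ΔswrA with SwrA) at the 20 wild-type DegU sites of largest fold over ΔdegU, by strain and antibody. At the site between ccdA and yneI the DegU value is 7.14 in wild type and 0.58 in ΔswrA, whereas between gdnE and EJJ34_RS21135 it is 4.42 and 4.97.

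With all DegU libraries in the fit, DegU was called at more sites in the strains meant to raise its activity. These strains also lacked pgsB coverage in WGS and had WGS in place of input as control. The contrasts with wild type thus cannot tell the constructs from those differences. Between bslB and the spore coat polysaccharide gene spsL, enrichment was 4.75 ± 0.21 (SD, n = 3) in wild type and 7.46 ± 1.26 (SD, n = 3) with Physpank-degQ, a rise of 2.72. Other rises with Physpank-degQ were 2.96 between ykhA and hmpA, a flavohemoglobin gene, 2.90 between the phosphate-binding protein gene pstS and pbpA, 2.80 between the transition-state regulator gene abrB and metG, and 2.47 between degQ and EJJ34_RS17370. With the strain labelled ΔdegU Physpank-degU32 the largest rises were 5.73 in yydB, 5.66 in yybL and 5.40 in ybbJ, with 4.96 between the sigma factor gene sigY and yxlA and 4.86 in the spore coat gene cotH. The same strain was lower than wild type by log2 at some of the strongest wild-type sites: −2.47 in yvyF, −2.00 between mcpA and tlpA and −1.72 between ccdA and yneI. The lists over ΔdegU held 223 sites with Physpank-degQ and 428 in the strain labelled ΔdegU Physpank-degU32. Over the 476 union sites, limma found 200 higher and 8 lower with Physpank-degQ than in wild type, and 393 higher and 7 lower in the strain labelled ΔdegU Physpank-degU32. Of the 476, 429 had no DegU call in wild type, so a majority higher was favoured by the choice of sites. At the 47 wild-type sites the counts were 18 higher, and 22 higher and 3 lower. Without division by the control, 244 of 420 union sites were higher and 3 lower with Physpank-degQ, and 382 and 4 in the other strain. Under scaling by total coverage, the median bin of the genome itself moved by −0.35 with Physpank-degQ and −0.54 in the strain labelled ΔdegU Physpank-degU32. With scaling by the median bin, 410 of 644 union sites were higher and 2 lower with Physpank-degQ. Lower sites numbered 14 without Physpank-degQ replicate 3, and 2 and 5 without wild-type replicates 1 and 3. The Physpank-degQ list rose to 336 sites without Physpank-degQ replicate 1 and fell to 64 with only both groups in the fit, where wild type had 78. Bins at least 2-fold below ΔdegU numbered 790 against 389 above it with Physpank-degQ, and 1721 against 890 in the strain labelled ΔdegU Physpank-degU32.

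Without swrA, DegU was lower at most of the strong wild-type sites, and at several it was no longer above the input. Between ccdA and yneI, enrichment went from 7.14 ± 0.20 (SD, n = 3) in wild type to 0.58 ± 0.46 (SD, n = 3) in ΔswrA, a change of −6.56 (SE 0.47, adjusted p = 1.26e-09, lower in 3 of 3 libraries). Between epr and sacX it went from 6.16 ± 0.40 to −0.13 ± 0.15 (SD, n = 3 each), and the changes were −5.81 in yrvJ, −4.80 between ftsZ and bpr, −4.71 between hxlR and srfAA, and −4.35 in yvyF. Between mcpA and tlpA, genes of chemotaxis receptors, DegU fell by 3.99 but stayed at 3.49 ± 0.71 (SD, n = 3). Other sites changed little: the values for ΔswrA minus wild type were 0.55 (adjusted p = 0.605) between gdnE and EJJ34_RS21135, −0.15 (adjusted p = 0.902) between yhzC and the competence regulator gene comK, and −0.04 (adjusted p = 0.946) between pbpE and the levansucrase gene sacB, the last 2 named in the ΔswrA list. limma found 62 of the 476 sites lower and 3 higher, and at the 47 wild-type sites 35 lower and 0 higher (0 at an unadjusted p under 0.05), with a median of −2.28. The 47 sites were chosen for high values in the same wild-type libraries, so lower values in ΔswrA were favoured there. The 3 higher sites, in ilvD (0.95), fabD (0.65) and phyC (0.56), were no longer called without division by the control (0.36, 0.18 and 0.31). The call in fabD also ended without ΔswrA replicate 2 (0.61) or 3 (0.56) or wild-type replicate 2 (0.55). In phyC it ended without ΔswrA replicate 1 (0.57), 2 (0.57) or 3 (0.53) or wild-type replicate 2 (0.50) or 3 (0.56). Of the 62 lower sites, 22 lay where the crosslinked input itself was at least 2 times WGS. Without division by the control 43 of 420 union sites were lower, with the number-matched control 39 of 464, and with only both groups in the fit 39.

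In the ΔswrA strain itself, 22 sites were called over ΔdegU. They came from 34 bins at least 2-fold above it, while 555 bins lay as far below it. The largest fold was 5.00 between gdnE and EJJ34_RS21135, followed by 3.74 between dgrA and ypeB, a gene of spore germination, 3.45 in tlpA, 3.28 between yxiB and the arabinanase gene abnB, 3.25 in EJJ34_RS17370 beside degQ, and 3.11 between codY and flgB. Sites were also called between yhzC and comK (2.93), between wapA, which encodes a contact-dependent toxin, and yxxF (2.75), and between pbpE and sacB (2.36). The count moved with the processing, to 1 site without division by the control or with the number-matched control, 7 with 1000 bp bins, and 14 with scaling by the median bin. It held 7 sites without ΔdegU replicate 2, 43 without ΔdegU replicate 1, and 45, 12 and 11 without ΔswrA replicates 1, 2 and 3. Without ΔdegU replicate 2, limma's call ended in tlpA (3.46), in EJJ34_RS17370 (3.21) and between codY and flgB (3.09, adjusted p = 0.0579). Between yxiB and abnB it ended without ΔdegU replicate 1 (3.22) or 2 (3.33) or ΔswrA replicate 2 (2.76) or 3 (2.89). Between wapA and yxxF it ended without ΔdegU replicate 1 (2.52) or 2 (2.98) or ΔswrA replicate 2 (2.17) or 3 (2.31).

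**Figure D2:**
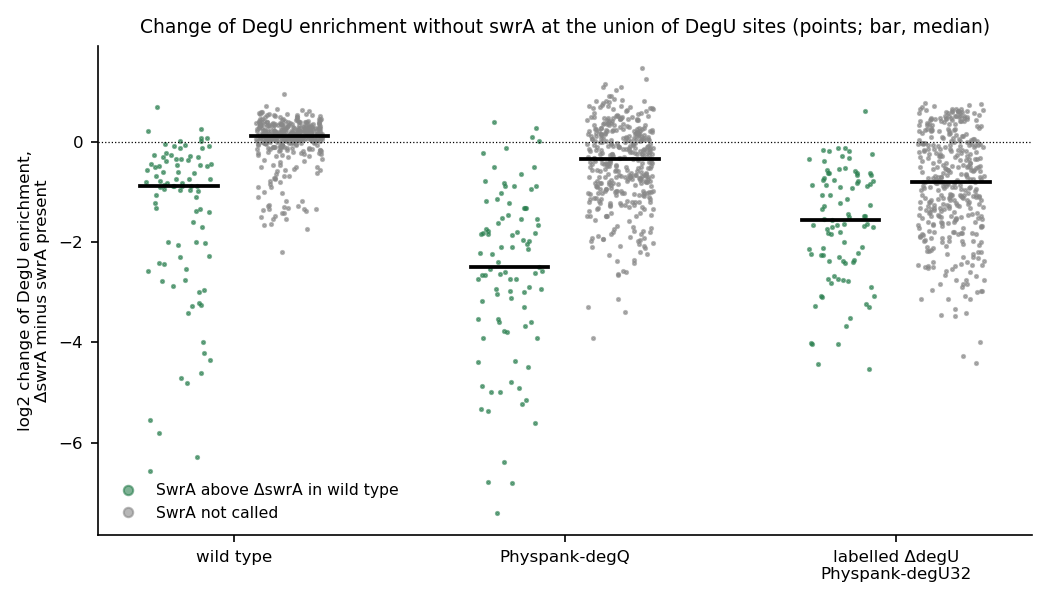
Change of DegU enrichment (log2, strain without swrA minus the strain with it, y axis) at each of the 476 union sites (points) in 3 backgrounds (x axis), with SwrA called above ΔswrA in wild type (green, 91 sites) or not (grey, 385 sites). Bars are medians, which are −0.88 and 0.12 in wild type, −2.50 and −0.34 with Physpank-degQ, and −1.55 and −0.80 in the strains labelled ΔdegU Physpank-degU32.

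With Physpank-degQ, the loss of swrA lowered DegU at more of the 476 union sites than in wild type, but not at more of the 47 wild-type sites. The largest changes were −7.40 between bslB and spsL (SE 0.48, adjusted p = 1.73e-10, lower in 3 of 3 libraries), −6.81 between ccdA and yneI, −6.79 between epr and sacX, and −6.40 in yrvJ. Between degQ and EJJ34_RS17370 the value was −2.57 (adjusted p = 0.000219), whereas between gdnE and EJJ34_RS21135 it was 0.55 (adjusted p = 0.354) and between ykhA and hmpA −0.12 (adjusted p = 0.872), both among the largest folds of the ΔswrA Physpank-degQ list. limma found 227 of the 476 union sites lower and 29 higher, and with scaling by the median bin 397 of 644 lower and 1 higher. Over ΔdegU, 223 sites were called with swrA and 41 without it, from the same libraries. A majority lower was thus favoured by the choice of union sites. At the 47 wild-type sites 34 were lower and 3 higher (median −3.04), against 35 lower in wild type. Of the 29 higher sites, 15 lay where the crosslinked input was at least 2 times WGS, srfAA and srfAB among them. Higher sites numbered 5 without division by the control, 16, 15 and 13 without ΔswrA Physpank-degQ replicates 1, 2 and 3, and 19 and 15 without Physpank-degQ replicates 2 and 3. The ΔswrA Physpank-degQ list over ΔdegU held 41 sites, with 6.18 between gdnE and EJJ34_RS21135 as the largest fold. Of the 41, 19 lay where the crosslinked input was at least 2 times WGS, and 20 were less than 2-fold above their own control. That list held 81 sites with only both groups in the fit, 25 without division by the control, 18 and 21 without ΔdegU replicates 1 and 2, and 26 and 25 without ΔswrA Physpank-degQ replicates 1 and 3. Between ykhA and hmpA the call over ΔdegU ended without ΔdegU replicate 1 (4.30).

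In the strains labelled ΔdegU Physpank-degU32, DegU remained above ΔdegU at many sites without swrA, at levels below those with swrA. Between yxiB and abnB the folds over ΔdegU were 7.90 with swrA and 7.62 without it, and the change was −0.18 (adjusted p = 0.84). Between epr and sacX enrichment was 6.12 ± 0.34 with swrA and 3.85 ± 0.28 without it (SD, n = 3 each), and between bslB and spsL it fell by 3.24 (adjusted p = 5.1e-06). The largest changes were −4.54 in ydfL, −4.43 in EJJ34_RS20020, −4.41 between scmK and EJJ34_RS21485, and −4.28 between yobL and yobM. The list without swrA held 260 sites, and limma found 279 of the 476 union sites lower and 10 higher, the higher ones all by less than 1. With swrA the list held 428 sites, from the same libraries, so a majority lower was favoured by the choice of union sites. At the 47 wild-type sites 25 were lower and 0 higher (0 at an unadjusted p under 0.05), with a median of −1.27. With 1000 bp bins 117 of 195 union sites were lower and 6 higher, and with a log2 fold of at least 2 for the union 166 of 257 were lower and 1 higher. With scaling by the median bin, limma found 432 of 644 union sites lower and 0 higher (2 at an unadjusted p under 0.05). Higher sites numbered 2 without division by the control, 19 with only both groups in the fit, and 5 without replicate 2 of the strain labelled ΔdegU Physpank-degU32. Bins at least 2-fold below ΔdegU numbered 195 in the strain without swrA, against 551 above it.

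The effect of losing swrA differed between backgrounds by limma's interaction term, over union sites of which 429 of 476 had no DegU call in wild type. At those 429, DegU in wild type stood at a median of 0.23 over ΔdegU, against 3.48 at the 47 wild-type sites. With Physpank-degQ, the change lay below that in wild type at 145 sites and above it at 22, and the lowest terms were −3.19 between pstS and pbpA, −3.02 in EJJ34_RS20020 and −2.91 between yisI and yisJ. In the strains labelled ΔdegU Physpank-degU32, it lay below at 216 sites and above at 33. The higher terms included 2 of the strongest wild-type sites, between epr and sacX (4.03) and in yvyF (3.48). At the 47 wild-type sites, the term was lower at 7 and higher at 3 with Physpank-degQ, and lower at 1 and higher at 14 in the strains labelled ΔdegU Physpank-degU32. Of the higher terms, 22 of 22 with Physpank-degQ and 22 of 33 in the other background lay where the crosslinked input was at least 2 times WGS. Without division by the control, 94 of 420 terms were lower and 1 higher with Physpank-degQ. With 1000 bp bins 67 of 195 were lower and 7 higher there, and 83 and 13 in the other background, where 13 were also higher without division by the control.

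SwrA was found at many of the sites bound by DegU. The largest log2 folds over ΔswrA were 7.73 in ccdA (SE 0.45), 7.65 between codY and flgB (SE 0.45, adjusted p = 0.000142, 1690801 to 1691600), 6.66 in yvyF, 6.05 between epr and sacX, 5.53 between bslB and spsL and 5.49 in tlpA. Between its own gene and ctpB, SwrA stood at 5.24. limma called 78 SwrA sites with a median fold of 2.26. Of these, 36 overlapped DegU sites of wild type, which are 46.2% of the SwrA and 76.6% of the DegU sites. Random placements of the SwrA sites overlapped 0.583 on average and at most 4, and none of 1000 reached 36 (one-sided permutation p = 0.001, the smallest they can give). Over the 476 union sites, SwrA was above ΔswrA at 91 and below it at 1, in yeeK, where the direction turned without division by the control (0.43). Of the 47 wild-type DegU sites, 38 had SwrA, with a median fold of 3.10. Bins at least 2-fold below ΔswrA numbered 330 against 132 above it. The 78 sites became 11 and 15 without ΔswrA replicates 1 and 2 and 44 and 42 without wild-type replicates 2 and 3. Without ΔswrA replicate 1 the call between swrA and ctpB ended (4.89, adjusted p = 0.0615). The lower value in yeeK was no longer called without wild-type replicate 1 (−1.05), 2 (−0.91) or 3 (−1.08) or ΔswrA replicate 1 (−1.11) or 2 (−0.92).

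In the libraries labelled ΔdegU, SwrA was not detectable at these sites above the level in ΔswrA. Of the 3 libraries, the one labelled ΔdegU replicate 1 is in doubt by its low swrA coverage, and every mean below includes it unless it is said to be left out. Between ccdA and yneI, SwrA enrichment was 8.14 in wild type and −0.54 in ΔdegU. Between codY and flgB it was 6.93 ± 0.21 and −0.70 ± 0.68 (SD, n = 3 each), and between epr and sacX it was 5.83 and −0.65. All 78 SwrA sites were lower in ΔdegU than in wild type, with a median change of −2.48. The 78 were called for high values in the same wild-type libraries, so a fall at all of them was favoured by that choice. Against ΔswrA, limma called 0 of the 78 higher (1 at an unadjusted p under 0.05), with a median of −0.08. Without the library labelled ΔdegU replicate 1, all 78 were again lower than in wild type (median −2.10), and limma called 0 above ΔswrA (3 at an unadjusted p under 0.05, median 0.13). Over the 476 union sites, which were chosen without the SwrA libraries, SwrA fell at 121 and rose at 0 (2 at an unadjusted p under 0.05). Against ΔswrA, limma called 0 of them higher and 0 lower (2 and 10 at an unadjusted p under 0.05). Without that library SwrA fell at 123 of the union sites, and limma called 0 above ΔswrA (11 at an unadjusted p under 0.05). At 45 of the 47 wild-type DegU sites SwrA was lower in ΔdegU than in wild type, with a median change of −3.11. By bins, 126 were at least 2-fold lower and 0 at least 2-fold higher than in wild type (4 at any fold past limma's threshold). Against ΔswrA limma called 0 bins (1140 higher and 1409 lower at an unadjusted p under 0.05).

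At the fla/che promoter, the subject of the series title, the question was how far the presence of DegU depends on SwrA. The site spans 1690801 to 1692200 with its summit at 1691120, between codY and flgB. DegU enrichment was 5.45 ± 0.60 in wild type and 2.91 ± 0.66 in ΔswrA (SD, n = 3 each), which in relative coverage is 28.7 ± 12.9 and 4.03 ± 1.63 times the library mean. With Physpank-degQ it was 5.24 ± 1.16, and 3.14 ± 0.11 without swrA. It was 5.78 ± 0.24 and 4.25 ± 0.43 in the strains labelled ΔdegU Physpank-degU32 with and without swrA. In ΔdegU it was −0.15 ± 0.03 (SD, n = 2), so DegU stayed above the control in every strain without swrA. In ΔswrA, limma's call over ΔdegU ended without ΔdegU replicate 2 (3.09), without division by the control (2.69, adjusted p = 0.219) and with the number-matched control (3.14, adjusted p = 0.0554). The stratified exact permutation test gave a mean difference of −2.06, with a two-sided p = 0.00025, the smallest it can give. Within backgrounds the differences were −2.54, −2.10 and −1.53, lower in 3 of 3 libraries in each, with an exact permutation p = 0.1, the smallest 3 against 3 allow. In the strains labelled ΔdegU Physpank-degU32, relative coverage was 20.4 ± 3.32 with swrA and 13.9 ± 4.17 without it (SD, n = 3 each). There replicate 2 without swrA (18.4) lay above replicate 3 with it (16.9), so full separation rested on division by the control. For the 3 backgrounds, limma's adjusted p over the union sites was 0.00105, 0.00164 and 0.0127. Its interaction terms were 0.44 (adjusted p = 0.684) with Physpank-degQ and 1.01 (adjusted p = 0.262) in the strains labelled ΔdegU Physpank-degU32. With swrA present, DegU at this promoter did not differ detectably from wild type with Physpank-degQ (−0.21, adjusted p = 0.747) or in the strain labelled ΔdegU Physpank-degU32 (0.33, adjusted p = 0.548). Neither direction held. The first turned to 0.19 with scaling by the median bin, 0.45 without Physpank-degQ replicate 3 and 0.13 without wild-type replicate 1. The second turned to −0.0049 with a pseudocount of 0.5, −0.42 without division by the control and −0.62 with the other WGS libraries as control, and none of these was called. The interaction of 0.44 turned to −0.22 without Physpank-degQ replicate 3. In the strains labelled ΔdegU Physpank-degU32, limma's call for losing swrA ended without division by the control (−0.58, adjusted p = 0.341) and with the other WGS libraries as control (−0.59), where the interaction passed (2.23 and 1.96). It also ended with a pseudocount of 0.5 (−1.10), 1000 bp bins (−0.99) or without replicate 1 of the strain labelled ΔdegU ΔswrA Physpank-degU32 (−1.33, adjusted p = 0.0618).

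**Figure D3:**
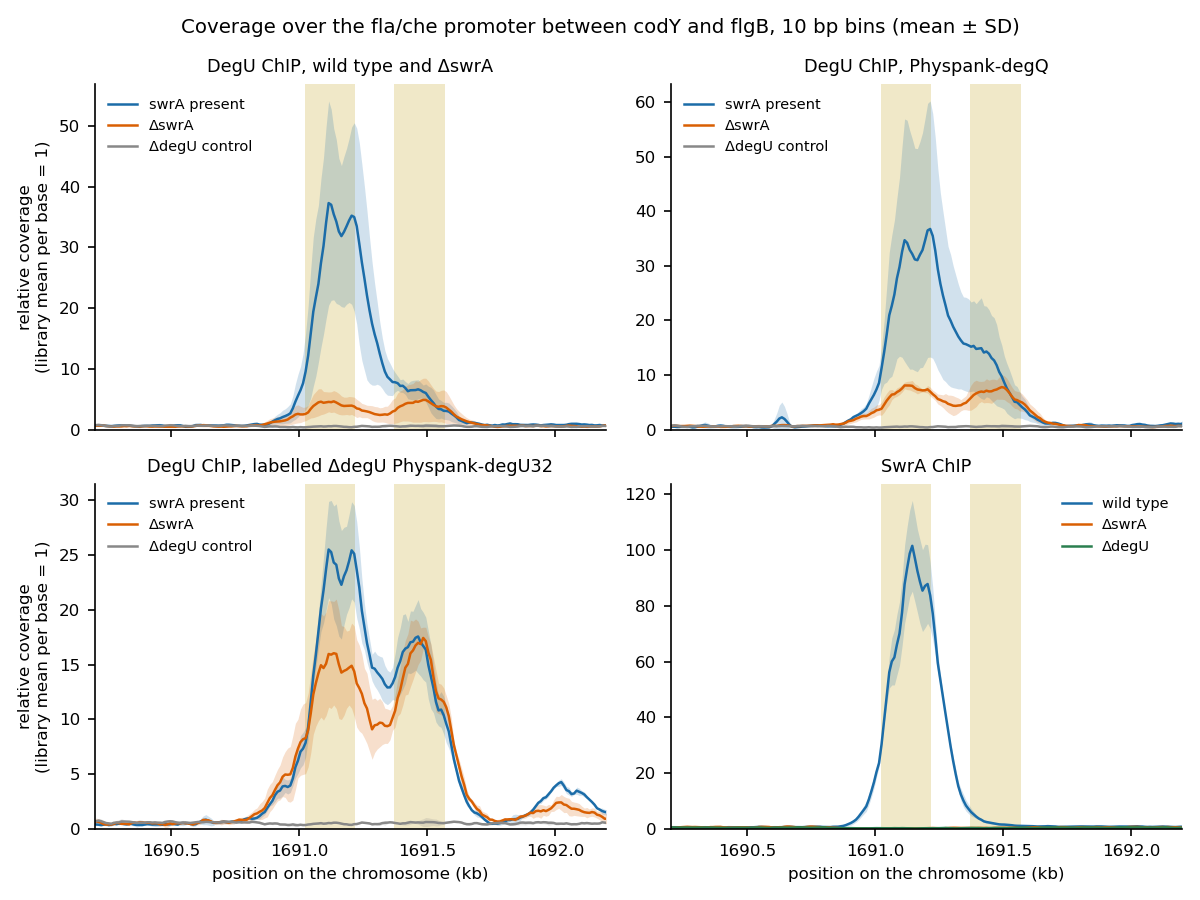
Relative coverage (library mean per base = 1, y axis) in 10 bp bins over the fla/che promoter (x axis, position in kb) as mean lines with SD bands, for DegU in 3 backgrounds with (blue) and without (orange) swrA and in ΔdegU (grey), and for SwrA in 3 strains. The shaded windows run from 1691021 to 1691220 and from 1691371 to 1691570, and mean DegU coverage in the left window is 28.7 in wild type and 4.03 in ΔswrA.

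**Figure D4:**
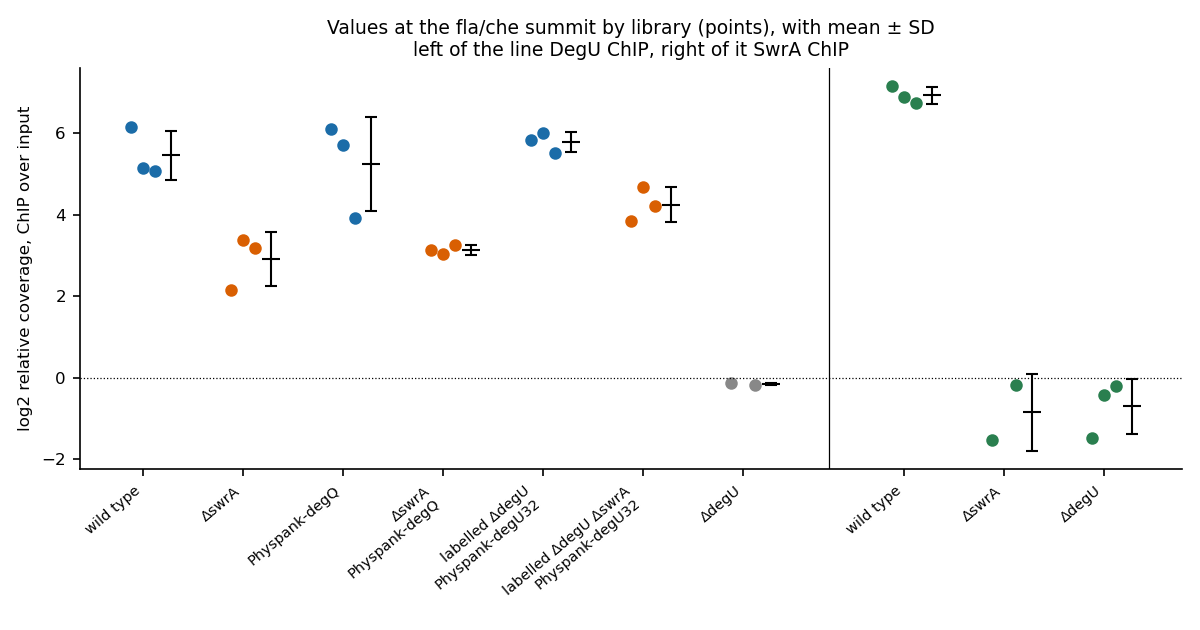
Enrichment (log2 relative coverage of ChIP over control DNA, y axis) in the 200 bp at the fla/che summit for each library (points) with mean ± SD, by strain (x axis), for DegU on the left and SwrA on the right. In each of the 3 backgrounds all 3 libraries without swrA lie below all 3 with it. In relative coverage not divided by the control, replicate 2 of the strain labelled ΔdegU ΔswrA Physpank-degU32 (18.4) lies above replicate 3 of that with swrA (16.9).

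The shape of DegU at the fla/che promoter was compared because the series title speaks of an extension of DegU by SwrA. Width at 0.5 of the summit height was 187 ± 32 bp in wild type and 227 ± 23 bp in ΔswrA, 247 ± 38 and 210 ± 35 bp with Physpank-degQ, and 230 ± 35 and 210 ± 10 bp in the strains labelled ΔdegU Physpank-degU32 (SD, n = 3 each). The mean difference was −5.56 bp (two-sided exact permutation p = 0.794), which does not show equal widths. In 4 of the 9 libraries without swrA, replicates 2 and 3 of ΔswrA and 1 and 3 of ΔswrA Physpank-degQ, the summit taken lay from 1691480 to 1691520, within flgB. With swrA it lay from 1691100 to 1691210, so these widths are of different maxima. At 0.25 of the summit height, where the width can take in both maxima, the direction turned, to 211 bp wider without swrA (exact permutation p = 5e-04). It also turned to 51.1 bp without division by the control (exact permutation p = 0.331), to 1.67 bp without Physpank-degQ replicate 2 and to 1.11 bp without ΔswrA Physpank-degQ replicate 2. The maximum within flgB, from 1691371 to 1691570, was singled out after its values were seen. There DegU was 3.19 ± 0.31 in wild type and 2.62 ± 1.53 in ΔswrA (SD, n = 3 each), 3.46 ± 1.12 and 3.12 ± 0.48 with Physpank-degQ, and 4.94 ± 0.26 and 4.12 ± 0.18 (SD, n = 3 each) in the strains labelled ΔdegU Physpank-degU32. The mean change over the 3 backgrounds was −0.58 (exact permutation p = 0.131), against −2.06 at the summit. The ΔswrA mean rested on replicate 1 (0.85, against 3.58 and 3.41), without which the change was −0.28 (exact permutation p = 0.308). Without Physpank-degQ replicate 3 the change was −0.79 (exact permutation p = 0.0135), so whether this maximum falls without swrA is open. The log2 ratio of summit to this maximum changed by −1.26, from 2.24 to 0.29 in wild type, from 1.37 to 0.08 with Physpank-degQ, and from 0.46 to −0.09 in the strains labelled ΔdegU Physpank-degU32. SwrA in wild type stood at 4.93 ± 0.39 (SD, n = 3) by the same ratio. As the window was chosen for the move of the summit, the ratio restates that move and is no test of shape.

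The gene lists asked which functions lie next to bound DNA. In wild type, 9 of 18 members of the flagellar and chemotaxis list were past the threshold for DegU (10 adjusted over the list alone), against 82 of 4300 genes (one-sided Fisher's exact test, adjusted p = 5.42e-11). Among them were mcpA (6.57) and tlpA (6.43), genes of chemotaxis receptors, epr (5.57) and flgB (4.95). mcpA and tlpA are neighbours with a union site between them, so they are not independent members. Of the secreted enzymes 3 of 17 passed (3 over the list alone, adjusted p = 0.0112), which were sacX (5.21), a gene of sucrose sensing that shares its intergenic region with epr, the protease gene bpr (4.44) and the levansucrase gene sacB (1.76). Of the competence genes 2 of 9 passed (2 over the list alone, adjusted p = 0.0237), which were srfAA (3.86), at the start of the surfactin operon that also carries comS, and comK (2.52). Of the Deg regulators 1 of 4 passed, degQ at 3.30 (2 over the list alone, adjusted p = 0.111), and of biofilm and capsule genes limma called 0 of 9 (0 over the list alone, 1 at an unadjusted p under 0.05). Of the housekeeping list 1 of 12 passed, ftsZ, which shares its intergenic region with bpr (adjusted p = 0.248). For SwrA in wild type the counts were 9 of 18 for the flagellar list (10 over the list alone, adjusted p = 3.23e-09), and 3 of 17 for the enzymes (4 over the list alone, adjusted p = 0.0387). They were 1 of 9 each for biofilm and competence (adjusted p = 0.286 each), 1 of 4 for Deg regulators (4 over the list alone, adjusted p = 0.228) and 1 of 12 for housekeeping. For SwrA in ΔdegU, with the library labelled ΔdegU replicate 1 included, limma called 0 of 4300 genes above ΔswrA (34 at an unadjusted p under 0.05) and 0 in each list (0 at an unadjusted p under 0.05).

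With Physpank-degQ, the flagellar list held 12 of 18 past the threshold (adjusted p = 3.55e-08), and the enzymes 6 of 17 (adjusted p = 0.00756). Biofilm and competence held 3 of 9 each (adjusted p = 0.0575 each), Deg regulators 4 of 4 (adjusted p = 0.000254) and housekeeping 2 of 12. In the strain labelled ΔdegU Physpank-degU32 the degradative enzymes held 11 of 17 (11 over the list alone, adjusted p = 5.38e-05). The subtilisin gene aprE was at 2.54 there (SE 0.25, adjusted p = 3.45e-07) and at 0.03 in wild type (adjusted p = 0.989), the xylanase gene xynA at 2.98 and 0.38, and the neutral protease gene nprE at 1.49 and 0.13. aprE and nprE, which encode the major extracellular proteases, are named outside the rule. The flagellar list held 12 of 18 in that strain (adjusted p = 2.75e-05), with the chemotaxis gene cheV at 4.33. Biofilm and capsule held 5 of 9 (adjusted p = 0.0159), among them the region beside pgsB at 4.44 and the biofilm regulator genes sinI at 2.64 and sinR at 2.63. WGS of that strain had next to no coverage of pgsB itself, so this member is a gene the strain may lack. Deg regulators held 4 of 4 (adjusted p = 0.0018), competence 3 of 9 (adjusted p = 0.233) and housekeeping 1 of 12.

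Without swrA, fewer members of the flagellar list passed in each background, though the difference between lists with and without swrA was not tested as such. Passing genes among all 4300 also fell, from 82 to 74 in wild type and from 414 to 50 with Physpank-degQ. In the strains labelled ΔdegU Physpank-degU32 they fell from 746 to 453. In ΔswrA, 3 of 18 flagellar genes passed (adjusted p = 0.0199), which were mcpA (2.93), tlpA (2.81) and flgB (2.68), and epr was not among them. Of the other lists 1 member each passed, sacB (1.73), bslA, which encodes the surface protein of biofilms (1.39), comK (2.54) and degQ (2.60). Over the list alone, 2 biofilm genes and 4 Deg regulators passed. Of housekeeping limma called 0 (0 at an unadjusted p under 0.05). In ΔswrA Physpank-degQ the flagellar list held 4 of 18 (adjusted p = 0.000264), and the enzymes, biofilm, competence and Deg regulators 1 each (2, 3, 1 and 4 over the list alone). Of housekeeping limma called 0 there (0 at an unadjusted p under 0.05). In the strain labelled ΔdegU ΔswrA Physpank-degU32 the flagellar list held 7 of 18 (8 over the list alone, adjusted p = 0.00233), the enzymes 7 of 17 (9 over the list alone, adjusted p = 0.00223), with xynA at 2.96 and aprE at 2.29. Biofilm and capsule held 5 of 9 (adjusted p = 0.00223), competence 1 of 9, and Deg regulators 4 of 4 (adjusted p = 0.00073). Of housekeeping limma called 0 (1 at an unadjusted p under 0.05).

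**Figure D5:**
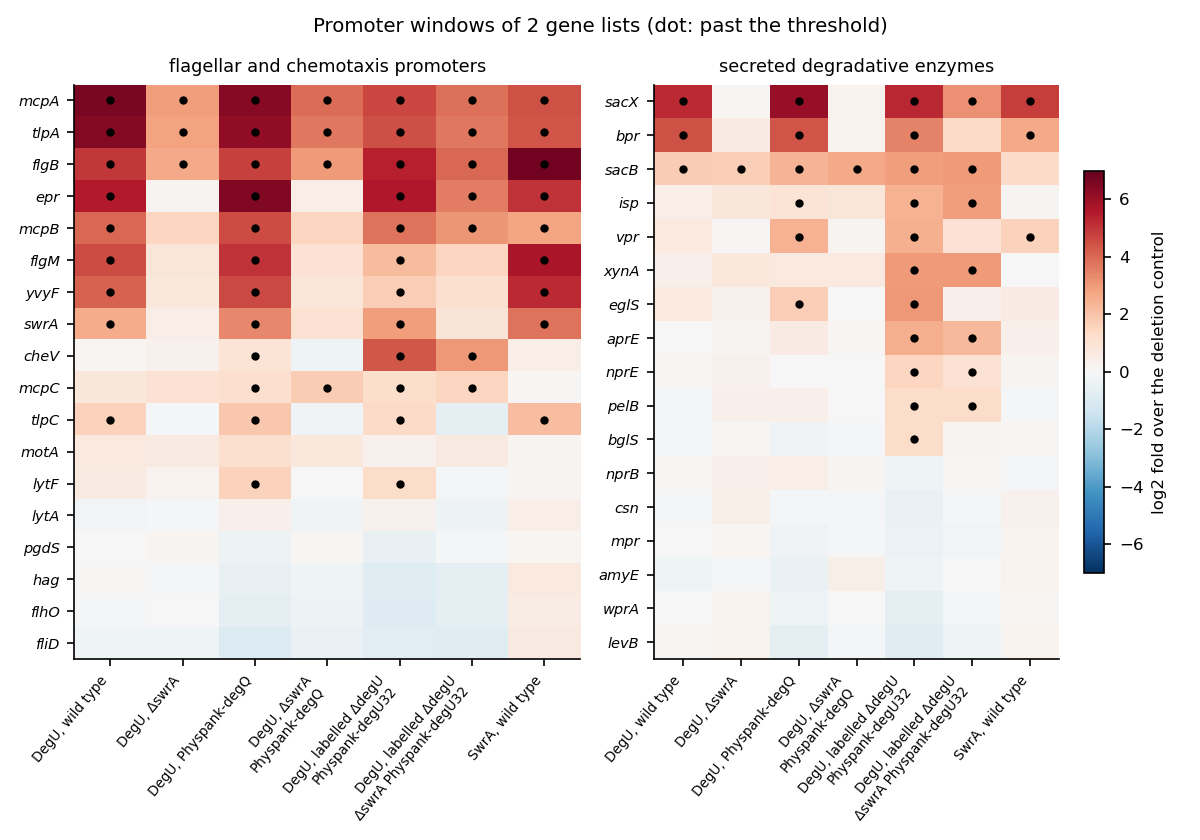
Log2 fold over the deletion control (colour) in the window at the gene end taken for each member of 2 gene lists (rows of cells) by strain and antibody (columns), with a dot where the fold was at least 0.5 and limma's adjusted p under 0.05. Dots number 9 of 18 and 3 of 17 for DegU in wild type and 12 of 18 and 11 of 17 in the strain labelled ΔdegU Physpank-degU32.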

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

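The tests of input over-representation, ChIP yield, WGS coverage and degU copies, and the splits of 12 libraries, were chosen only after the results were seen, and the splits of 6 libraries were planned.

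Losing swrA had an effect on DegU that differed between backgrounds, as the interaction term shows at 22 sites above and 145 below wild type with Physpank-degQ and at 33 above and 216 below in the strains labelled ΔdegU Physpank-degU32. Only 7 of the 145 and 1 of the 216 lower terms lie at the 47 wild-type sites. At the other 138 and 215, DegU in wild type stood at a median of only 0.28 and 0.11 over ΔdegU and had little to lose, so the direction there may follow from the choice of sites. At the 47 sites 3 and 14 terms lie above. The sites above include srfAA (2.98) and srfAB (2.89), and 44 of the 55 such calls, or 80%, lie where crosslinked input coverage is at least 2 times WGS, as only 27 of the 476 sites (5.67%) do. By background these were 22 of 22 with Physpank-degQ and 22 of 33 in the other. Both terms use the same libraries of wild type and ΔswrA, so the 55 calls can count a site in both. Without division by the control, only 1 of the 22 and 12 of the 33 lay at a union site at all, and each of these was called higher again. Stretches over-represented in the crosslinked input, which stands as control for wild type and ΔswrA but not for the Physpank strains, may therefore account for most of the sites above, and a biological difference stays open for sites elsewhere, such as between epr and sacX (4.03) and in yvyF (3.48). For the whole terms, the additive effects of swrA and background were removed before the 12 libraries were split anew. The real split alone, 1 of 100, gave as many sites with Physpank-degQ (167, highest other 121) and in the other background (249, highest other 237). The values split were already divided by each strain's control, which its libraries share. Chance error in a control thus stays in the real split, so chance is not excluded for the counts. The splits also say nothing of the choice of sites. Without removal of the additive effects, the splits mix them into the spread within groups, and their highest counts of 151 and 395 decide nothing about the interaction.

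DegU was lower without swrA at most wild-type sites, and a lower ChIP yield in the ΔswrA libraries was weighed against an effect of SwrA on DegU. At the 6 wild-type sites above their own input and without a SwrA call the median change was −0.50 (from −2.19 to 0.55, 2 of 6 lower), against −2.67 at the 38 with one (30 lower). These groups were not matched for strength. Wild-type sites that overlapped a SwrA site reached 7.41 over ΔdegU, and the others at most 4.49, between gdnE and EJJ34_RS21135, where ΔswrA stood at 5.00. A lower yield can take less log2 from a weak site, so the medians do not decide on yield. The other backgrounds were not tested so. Over the union sites, medians without and with a SwrA call were −0.34 and −2.50 with Physpank-degQ. They were −0.80 and −1.55 in the strains labelled ΔdegU Physpank-degU32, so yield stays open there too. The WGS library of the strain labelled ΔdegU Physpank-degU32 has 895 bins (4.25%) at or under 0.5 of the mean of the other 3 WGS libraries, which have at most 14 by the same measure, and with the mean of the other 3 as control 227 of 455 union sites were lower, with 210 of the 279 called lower again among them, which argues against these dips as the whole cause in that background. The amount of DegU protein in each strain was not measured in these data, so a change in it stays open, as does an effect of SwrA on binding.

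In WGS of both strains labelled ΔdegU Physpank-degU32, the control DNA of their ChIP libraries, degU stood at 2.17 and 2.03 times its flanks. A single added copy, as the labels read, would give about 1, and the lower value of 2.03 argues against it. A native degU beside the added copy would give 2.10 and 2.06 from the coverage around amyE. That is a candidate explanation, and an insertion present more than once stays open too, since no reads were analysed.

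The other terms with the largest size were −3.19 between pstS and pbpA, −3.02 in EJJ34_RS20020 and −2.91 between yisI and yisJ with Physpank-degQ, and −4.55 between yobL and yobM, −4.32 between scmK and EJJ34_RS21485 and −4.25 between fakA and sdaAB in the strains labelled ΔdegU Physpank-degU32. The highest coverage of a crosslinked input over WGS in a 200 bp bin was 28.0.

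The 6 libraries of each pair of strains split in 10 ways, too few for a share under 0.05, and 1 split, the real one, gave as many sites in each case. The real count and the highest other were 65 and 0 for losing swrA in wild type, 256 and 0 with Physpank-degQ, and 289 and 18 in the strains labelled ΔdegU Physpank-degU32. They were 208 and 53 for Physpank-degQ against wild type, 400 and 0 for the strain labelled ΔdegU Physpank-degU32 against wild type, and 121 and 0 for SwrA in ΔdegU against wild type, with the library labelled ΔdegU replicate 1 included.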

How the results depend on the processing

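Sites also above their own input and the mean of the other 3 WGS libraries were chosen after the data were seen, as was the shared count without division by the control. The fall of DegU at the fla/che promoter without swrA kept its direction and its test under every setting tried (−2.42 to −1.42, p at most 5e-04) and with each library left out (−2.28 to −1.92). Of the summary results, 146 values under other settings stayed within their limits, 45 counts moved by over 1.5 times and 2 turned, and with a library left out 118 stayed, 16 moved and 2 turned. Of 1683 comparisons of 187 named values, 1542 kept direction and call, 129 lost the call, 2 gained it and 10 turned. The cause was not tested except where stated. Several settings call the union of DegU sites anew, so a moved count of changed sites need not be a moved share. The union held 476 sites in the main fit, 644 with scaling by the median bin and 396 with a pseudocount of 0.5. It held 195 with 1000 bp bins, 420 without division by the control, 464 with the number-matched control and 257 with a log2 fold of at least 2.

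With only the compared groups in the fit, which leaves fewer libraries for the spread, the site lists were 78 in wild type, 64 with Physpank-degQ and 81 in ΔswrA Physpank-degQ, sites changed by losing swrA in wild type 42, and those changed by Physpank-degQ 92. With scaling by the median bin, the ΔswrA list held 14 sites, losing swrA with Physpank-degQ changed 398 and in the labelled ΔdegU Physpank-degU32 strains 432, Physpank-degQ against wild type 412, and the interaction with Physpank-degQ 253. A pseudocount of 0.5 gave 14 ΔswrA sites. Bins of 1000 bp, which dilute a narrow peak, gave lists of 26 (wild type), 88 (Physpank-degQ), 182 (labelled ΔdegU Physpank-degU32), 7 (ΔswrA), 19 (ΔswrA Physpank-degQ), 102 (labelled ΔdegU ΔswrA Physpank-degU32) and 37 (SwrA). They gave 38, 116 and 123 sites changed by losing swrA in the 3 backgrounds, 87 and 163 changed by Physpank-degQ and in the strain labelled ΔdegU Physpank-degU32, interactions of 74 and 96, and 59 sites with SwrA. No division by the control gave lists of 1 (ΔswrA), 25 (ΔswrA Physpank-degQ) and 50 (SwrA), 43 sites changed by losing swrA in wild type, and 95 interactions with Physpank-degQ. With the number-matched control the lists were 1 (ΔswrA) and 27 (ΔswrA Physpank-degQ), and 39 sites changed by losing swrA in wild type. A log2 fold of at least 2, a stricter rule, gave lists of 104 (Physpank-degQ), 237 (labelled ΔdegU Physpank-degU32), 12 (ΔswrA), 25 (ΔswrA Physpank-degQ), 114 (labelled ΔdegU ΔswrA Physpank-degU32) and 46 (SwrA), with 167 sites changed by losing swrA and 224 against wild type in the labelled ΔdegU Physpank-degU32 background, and interactions of 111 and 138. Sites also above their own input were 21 in ΔswrA Physpank-degQ, and 38 changed by losing swrA in wild type. Width at the fla/che promoter turned from −5.56 to 211 bp at 0.25 of the summit height, where another maximum can be taken in, and to 51.1 bp without division by the control, and ran from −12.2 to 1.67 with a library left out. Shared DegU and SwrA sites went from 36 to 29 with scaling by the median bin, 28 with a log2 fold of at least 2 and 29 without division by the control.

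With a library left out, the lists ran from 22 to 59 (DegU in wild type), 204 to 336 (Physpank-degQ), 7 to 45 (ΔswrA), 18 to 33 (ΔswrA Physpank-degQ) and 11 to 62 (SwrA). Named values that turned were poxB with Physpank-degQ (−1.12) and yfkN with Physpank-degQ against wild type (0.65), both with 1000 bp bins, and SwrA in yeeK (0.43) and EJJ34_RS04115 in ΔswrA Physpank-degQ (−0.33), both without division by the control. Between codY and flgB 3 values turned, none of them called. Physpank-degQ against wild type turned to 0.19 with scaling by the median bin and to 0.13 and 0.45 with a library left out. The strain labelled ΔdegU Physpank-degU32 turned to −0.0049 with a pseudocount of 0.5, −0.42 without division by the control and −0.62 with the other WGS libraries. The interaction with Physpank-degQ turned to −0.22 with a library left out. Of the gene list counts, 4 moved. A window from 200 bp outside to the gene end gave 0 biofilm genes for SwrA (1 before), 2 Deg regulators in wild type (1 before) and 2 housekeeping genes in the strain labelled ΔdegU Physpank-degU32 (1 before), and scaling by the median bin gave 3 of the last. A replicate block moved no count by over 1.5 times (wild type 49, SwrA 80, losing swrA in wild type 66). Of 18 correlations between equal replicate numbers, from −0.27 to 0.22, 2 were over 0.1, so the numbers do not pair libraries. Scaling by total coverage placed the median bin at 0.20, 0.41 and 0.34 for losing swrA in the 3 backgrounds, against −0.04, −0.01 and −0.01 when scaled by the median bin.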

Other observations

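The following values were chosen after the data were seen. In the strain labelled ΔdegU ΔswrA Physpank-degU32, the largest folds over ΔdegU after that between yxiB and abnB were 6.06 between EJJ34_RS01675 and ycdB, 5.80 between yfjA and the maltose utilisation gene glvA, 5.56 between ykhA and hmpA, and 5.37 between sigY and yxlA. With Physpank-degQ, losing swrA lowered DegU at 80 of the 91 union sites with SwrA and at 147 of the 385 without it, in wild type at 37 and 25, and in the strains labelled ΔdegU Physpank-degU32 at 63 and 216. In wild type, 22 of those 25 lay where the crosslinked input was at least 2 times WGS, as 0 of the 91 sites with SwrA did. Of the lower sites in the other backgrounds, 0 with Physpank-degQ and 1 in the strains labelled ΔdegU Physpank-degU32 lay there.

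Coverage of the 4 WGS libraries of the Physpank strains was next to absent over 2 stretches. One lies within amyE, the usual site for insertion of constructs, from 328231 to 328610 (380 bp). The other takes in the capsule synthesis gene pgsB, from 3699091 to 3700600 (1510 bp, and 1520 bp in 1 of the 4).

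Crosslinked inputs differed in how many of 20843 bins stood at least 4-fold above WGS. There were 691 in replicate 2 of the ΔswrA input for DegU, 462 in wild-type input replicate 2, 325 in replicate 2 of the ΔdegU input for SwrA, 148 in wild-type input replicate 3, and 19 to 55 in the others. In the mean of the wild-type inputs the highest were in srfAA (11.3), srfAB (10.2), EJJ34_RS04115 (9.97), yfnC (9.30), chrA (9.08) and gabT (9.06).

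Replicates of Physpank-degQ correlated over bins at 0.806 to 0.986 and those of SwrA ChIP labelled ΔdegU, with replicate 1 whose swrA coverage is low, at 0.516 to 0.886, against 0.898 to 0.982 for DegU in wild type, across bins, which are not independent replicates. At the fla/che summit, Physpank-degQ replicate 3 stood at 3.92 against 6.11 and 5.70 in replicates 1 and 2, and ΔswrA replicate 1 at 2.15 against 3.39 and 3.19.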
